A study of Drosophila melanogaster with 6 samples.

How the data were processed

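The 6 arrays measured total RNA of Drosophila S2 cells 48 h after a control transfection (2 arrays) or transfection with 10 ng (2 arrays), 30 ng (1 array) or 100 ng (1 array) of pAc-Clk. Groups and replicate numbers come from the sample titles. Per the labels, RNA was extracted with TRIzol and biotin-labelled for Affymetrix arrays. The submitters' processing notes name GCRMA, without a version or settings. The deposited values are intensities on a linear scale, one column per array, and no column was left unassigned (0 columns). Scanner files were not used here.

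The scale of the deposited intensities was settled from the values before any test was run. At face value their log2 reaches 22.86 and 8701 of 113712 values exceed a 16-bit scanner, whereas their natural log spans 1.69 to 15.85 and 0 values exceed it. The 4 kinds of hybridisation control, set against nominal relative concentrations taken from general knowledge of the array maker's mix, gave a mean slope of 0.96 if the natural log is read as log2 and 1.38 at face value. On the 100 ng array the slopes were 0.80 and 1.15, so there face value lay closer to 1; on the other arrays they were 0.97 to 1.05 and 1.40 to 1.51. The natural log was therefore used as the log2 GCRMA value; this is an inference, and the base of the back-transformation is not given in the sources used here. It departs from the fixed design, which named log2 of the deposited value as the fallback. That reading is given as an alternative: it multiplies every log2 change by 1.44, and its filter admits more dim probe sets, which changes the calls.

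Probe sets with a value of 4 or more on at least 2 of the 6 arrays were tested (8446), and 183 control probe sets were left out. Of the other probe sets 13647 carried 1 gene symbol in the platform annotation, 402 several and 4720 none, and 13544 symbols were updated by Entrez ID. The brightest probe set by mean over all arrays stood for each gene (6612 genes), and probe sets with several or no symbols were tested and counted only as probe sets. No genome coordinates are given, because the annotation build is not given in the sources used here. As a background reference, the highest Tag control probe set of each array was used; a gene under it on both controls has only a bound on its fold, set against the mean of these 2 values.

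Tests used limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with an intensity trend) with the data.table package (version 1.17.8), and Benjamini-Hochberg adjusted p under 0.05 over probe sets within each of 5 comparisons: each dose against control, the mean of the 3 doses against control, and the slope on log10 dose with its own control mean. For the comparisons against control, one coefficient per group left 2 residual degrees of freedom, with 7.60 prior degrees of freedom. The slope was fitted separately, with a control mean, a Clk mean and the slope, and had 3.47 prior degrees of freedom. Its residual also holds any departure from a straight line on log10 dose, so its p-values do not measure the spread between replicates alone. The single 30 and 100 ng arrays were assumed to vary like the replicated groups. Gene lists (22 lists, 457 of 461 genes matched to a current symbol) were tested with camera at a correlation of 0.01 where at least 3 members were tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

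The comparisons, lists, filters and most alternatives were chosen before the data were examined. So was the rule for named genes: every core clock gene and clock kinase or phosphatase; the 15 largest rises and 10 largest falls among called genes with all 4 Clk arrays beyond both controls over all doses; the 5 steepest slopes each way; and up to 4 members of each other list with the smallest p. Alternatives chosen after seeing the data were the face-value reading of the scale, alone and with robust moderation, leaving out both single-array doses, the 5' minus 3' control signal as a covariate, and list tests at 10 ng and at face value.

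The scripts were tested on simulated data with 200 changed probe sets among 8446. A log2 change of 1 was recovered in 84.0% of cases over all doses, 69.2% at 10 ng, 48.3% at 30 ng, 45.7% at 100 ng and 49.6% for the slope. A log2 change of 2 was recovered in at least 97.8% of cases in each of the 5 comparisons, and 4.15% to 5.58% of calls were false. These simulations hold no loss of 5' signal. The replicates were not copies: 5 of 18952 values were identical between the control arrays and 6 between the 10 ng arrays.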

Results

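RNA abundance was measured on 6 Affymetrix arrays in Drosophila S2 cells, a haemocyte-like line derived from late embryos. The cells had received either a control transfection or pAc-Clk, a plasmid for expressing Clk. Clk is the bHLH-PAS transcription factor that pairs with Cyc to drive transcription of clock genes, and RNA was taken 48 h after transfection. The control transfection and 10 ng of pAc-Clk had 2 arrays each, whereas 30 ng and 100 ng had 1 array each, so the number of arrays limits the precision. Nothing in the labels says that the replicates were separate cultures, so p-values measure the spread between these arrays, which may be technical. Of 18952 probe sets on each array, 8446 passed the signal filter, and they represented 6612 genes by 1 probe set each. Values are on a log2 scale that was inferred from the data, because the base of the deposited values is not stated. If the deposited values were instead taken at face value, every log2 change would be 1.44 times as large.

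The transfected gene was examined first. The Clk probe set read 2.50 and 2.84 on the control arrays, 3.46 and 3.47 at 10 ng, 5.07 at 30 ng and 4.66 at 100 ng. Both control values lay under the highest of the array's Tag control probe sets, which detect no fly transcript (2.96 and 2.97), so only bounds can be given for the fold. Clk was at least 1.41-fold higher at 10 ng (adjusted p = 1.00, unadjusted p = 0.00278), at least 4.29-fold higher at 30 ng (adjusted p = 0.000153) and at least 3.23-fold higher at 100 ng (adjusted p = 5.84e-05). At 10 ng it passed in 1 of 20 settings, with the replicate block (adjusted p = 0.0288), where the prior degrees of freedom were infinite. These bounds set each Clk mean against the mean of the highest Tag signals of the control arrays. On the Clk arrays the highest Tag signals were 2.95 and 3.22 at 10 ng, 3.18 at 30 ng and 3.56 at 100 ng. Against an array's own background the rise would be smaller on all but the first of these, so they are not bounds in that sense. Whether this probe set lies in the part of the transcript that the plasmid carries is not known here, so it may read the cell's own gene alone.

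At 10 ng, the dose with replicates, 4 of 6612 genes rose and 0 fell against the control transfection (limma, Benjamini-Hochberg adjusted p). tim, whose product dimerises with Per and represses Clk-Cyc, rose from 3.65 ± 0.54 to 8.37 ± 0.27 (SD, n = 2 each), a log2 change of 4.72 (SE 0.27, 26.4-fold, adjusted p = 5.28e-05). Timp, an inhibitor of matrix metalloproteinases, rose from 4.17 ± 0.035 to 7.80 ± 0.23, a log2 change of 3.62 (SE 0.22, adjusted p = 5.28e-05). The mucin-related gene Mur2B rose by 2.32 (SE 0.22, adjusted p = 0.00225) and CG10514 by 1.67 (SE 0.21, adjusted p = 0.0160). Second probe sets of tim and Timp also rose, as did 2 probe sets without a gene symbol here (2.06 and 2.27). The second probe set of tim read 2.13 and 2.53 in controls, under the highest Tag control. At 10 ng it was 10.8-fold above the mean of the controls' highest Tag signals. That of Timp rose by 4.94, from 2.68 and 3.14 in controls, of which only the second lay above the highest Tag control of its array. The 4 genes were named because they passed, outside the rule for named genes, although that rule also picks each of them at all doses. At an unadjusted p under 0.05, 26 genes were higher and 104 lower. These 130 of 6612 genes are fewer than that threshold would give by chance, so they are no evidence of further changes. The median log2 change of all genes was -0.09, and 0.007 after quantile normalization, so the excess of lower genes may follow array scaling.

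Among the other core clock genes at 10 ng, vri, which encodes a bZIP repressor of Clk, differed by 1.29 (SE 0.23, adjusted p = 0.175). It passed in 5 of 21 settings (adjusted p from 1.37e-08 to 0.986, log2 change 0.99 to 1.86), with a filter at 6, median centring, robust moderation, the replicate block or without control replicate 2. With the filter at 6, the replicate block or without control replicate 2 the prior degrees of freedom were infinite, so the spread of vri itself did not count. The changes of the other genes were 0.28 for per, 0.17 for Pdp1, -0.05 for cwo and -0.24 for cyc, and none of these passed. Of 7 core clock genes tested, 1 rose, and 3 did when adjusted over the list alone (tim, vri and Clk). cry was not tested, as its probe set stayed between 2.35 and 2.69 on the 6 arrays. cwo, a repressor of the same targets, read 8.54 and 10.49 on the 10 ng arrays, and that spread of 3.86-fold leaves a change of moderate size undetectable. The core clock list was shifted up as a set (camera adjusted p = 4.85e-23 with a preset correlation of 0.01), but its adjusted p was 0.210 with an estimated correlation. The list holds Clk, the transfected gene, and its median change was 0.28, against 4.72 for tim. The set result therefore rests largely on tim and includes the transfected gene.

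The 10 ng calls depended on which dim probe sets were tested and on each of the 10 ng arrays. The same 4 genes passed without the 30 or the 100 ng array. Each of these doses has its own coefficient, so leaving it out cannot move the 10 ng changes and is no separate support. Leaving out either control array kept these calls and added others. The prior degrees of freedom were then infinite, so a gene's own spread did not enter its p-value. Without 10 ng replicate 1 or 2 they were 4.35 or 4.41. Calls with a control array left out therefore cannot be compared with those with a 10 ng array left out. With no filter, 0 genes passed (354 at an unadjusted p under 0.05, smallest adjusted p = 0.448), and 0 passed when the deposited values were taken at face value, the fallback reading of the fixed design (246 unadjusted, smallest adjusted p = 0.119). Over 21 settings, tim passed in 17 (adjusted p from 2.71e-96 to 0.604), Timp in 18 (4.70e-48 to 0.448), Mur2B in 15 (1.18e-16 to 0.604) and CG10514 in 12 (4.53e-09 to 0.621). The lowest adjusted p of tim came with the filter at 6, where the prior degrees of freedom were infinite. Over the same settings the log2 change was 3.59 to 6.81 for tim, 2.81 to 5.23 for Timp, 1.67 to 3.35 for Mur2B and 0.85 to 2.41 for CG10514, lowest with the pseudocount and highest at face value. Timp was the 1 gene left without 10 ng replicate 1, and Timp and tim the 2 left without replicate 2 or with the 5' control signal as a covariate, whereas 12 passed without control replicate 1, 8 without control replicate 2 and 10 with robust moderation.

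**Figure D1:**
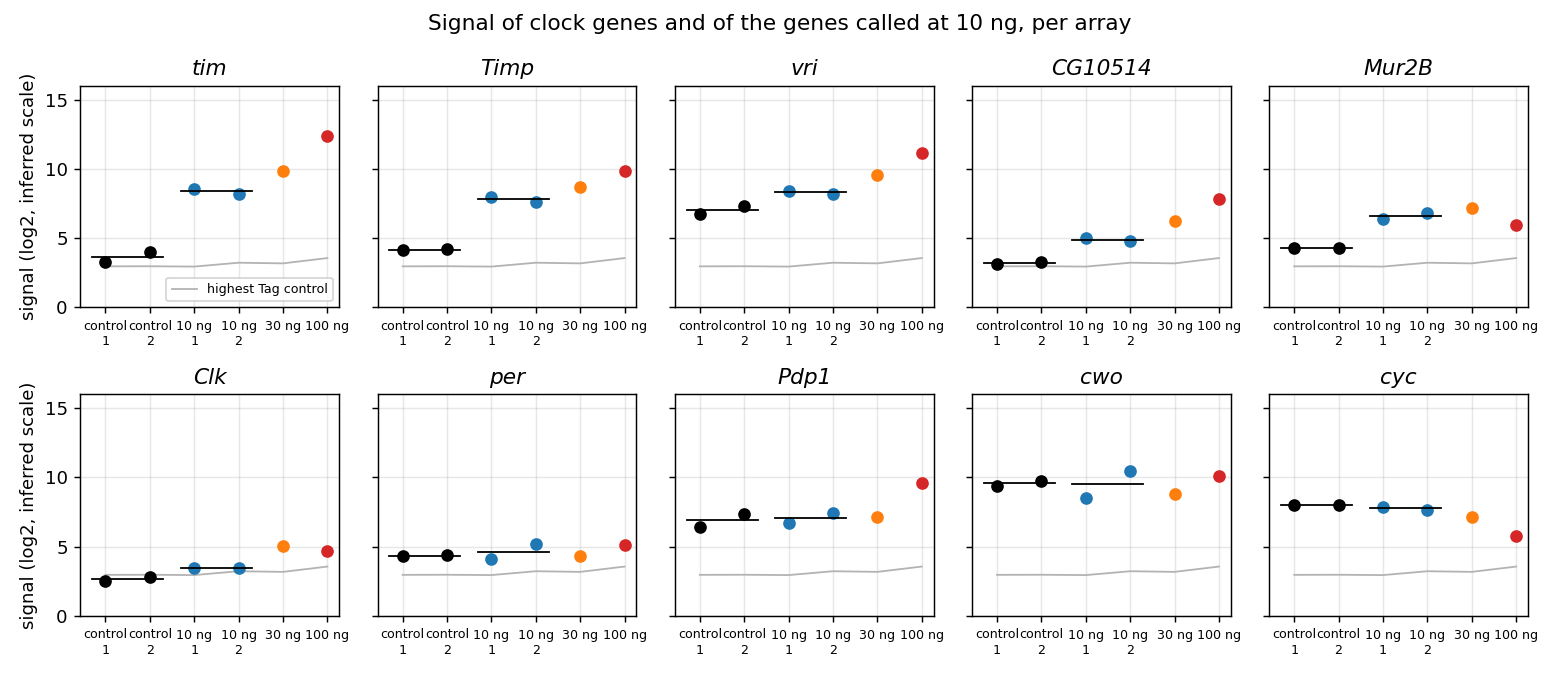
Signal on the inferred log2 scale (vertical axis) of 10 genes on each of the 6 arrays (horizontal axis), with points for arrays, black bars for the means of the 2 control and the 2 10 ng arrays, and a grey line for the highest Tag control of each array. tim goes from 3.65 in controls to 12.35 on the 100 ng array, whereas cwo differs between the 10 ng arrays (8.54 and 10.49).

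The 5' signal of control transcripts was low on the 30 and 100 ng arrays. The array carries probe sets at the 3' end, the middle and the 5' end of 3 abundant fly transcripts, for actin, eIF-4a and GAPDH. The mean 5' minus 3' signal was -0.75 ± 0.0040 in controls and -0.94 ± 0.43 at 10 ng (SD, n = 2 each), against -9.40 at 30 ng and -8.25 at 100 ng. The 5' signal relative to the 3' signal was thus 401-fold lower at 30 ng and 181-fold lower at 100 ng than in controls. The middle probe sets fell relative to the 3' ones by 2.36 at 30 ng and by 6.09 at 100 ng. Each of these doses is a single array, so dose and this loss of 5' signal cannot be told apart.

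**Figure D2:**
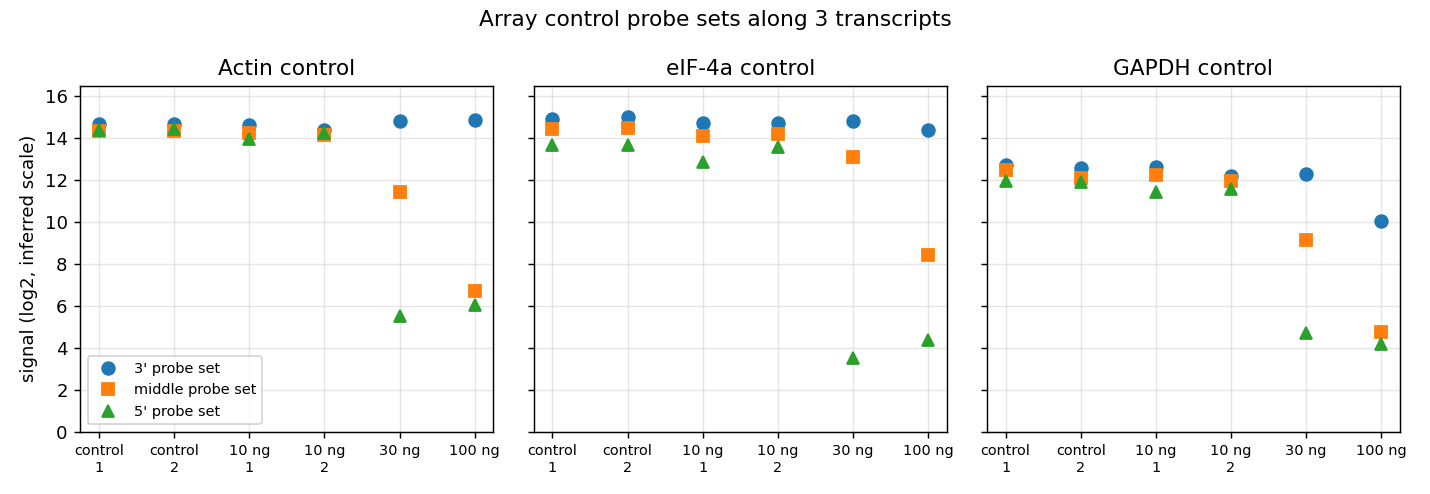
Signal on the inferred log2 scale (vertical axis) of the 3', middle and 5' probe sets of 3 control transcripts, one panel each, on each of the 6 arrays (horizontal axis); each point is 1 array. On the 30 and 100 ng arrays the 5' points lie between 3.50 and 6.06, against 11.45 to 14.42 on the other arrays.

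At 30 ng, 411 genes were called higher and 686 lower, and at 100 ng 2309 were called higher and 2338 lower, on the assumption that each single array varies like the replicated groups. tim rose by 6.20 at 30 ng and by 8.71 at 100 ng, vri by 2.55 and 4.13, and CG10514 rose 8.03-fold and 24.6-fold. Timp rose by 4.52 and 5.69 by its brighter probe set, while its second probe set rose by 4.79 and 2.77. Mur2B rose by 2.93 at 30 ng and by 1.68 at 100 ng. Pdp1, a bZIP activator of Clk, rose at 100 ng by 2.70 (SE 0.40, adjusted p = 0.000185), and cyc fell by 0.85 at 30 ng and by 2.22 at 100 ng. per differed by -0.03 and 0.81 and cwo by -0.73 and 0.53, which did not pass. All of these calls come from the arrays whose 5' minus 3' control signal was -9.40 and -8.25.

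Calls at the 3 doses overlapped. The 4 genes called higher at 10 ng were also called higher at 30 ng and at 100 ng, where independent lists would share 0.249 and 1.40. Between 30 and 100 ng, 358 higher calls and 660 lower calls were shared, against 143.5 and 242.6 for independent lists. In 50 simulations of unchanged groups against the same controls, the mean number shared was at most 0.10, but almost nothing is called in such data, so this says little about lists of this size. The 2 control arrays are too few to split, so part of the excess may come from the shared controls. The 30 and 100 ng arrays also share the low 5' control signal (-9.40 and -8.25). The split of the 30 ng calls depended on scaling: 37.5% were higher in the values as deposited, against 54.7% after quantile normalization and 51.6% after median centring. The 30 ng count was 450 with no filter and 456 at face value.

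Over all doses together, 1518 genes were called higher and 1777 lower than in the control transfection, in a contrast of the mean of the 3 dose groups against control. The rule for named genes took the 15 largest rises among called genes that were higher on all 4 Clk arrays than on both controls. tim was 6.54 higher (SE 0.24, adjusted p = 1.78e-07) and Timp 4.61 (SE 0.19, adjusted p = 2.84e-07). Next came CG10514 (3.10), vri (2.66), Mur2B (2.31), loh (2.08), which encodes an ADAMTS-like matrix protein, CG12177 (1.95), TfIIA-S-2 (1.91) and CG13248 (1.81). The last 6 were Clk (1.73), CG34165 (1.65), CG13640 (1.64), Mitf (1.64), cdi (1.63) and TTLL6A (1.61). Without the 100 ng array the calls of Mitf (0.57, adjusted p = 0.0752), cdi (0.58, adjusted p = 0.143) and TTLL6A (1.09, adjusted p = 0.0616) were lost. Clk and CG13640 read under the highest Tag control on both control arrays, so their changes are set by a value at background. Set against the highest Tag signals of the controls, Clk was at least 3.23-fold and CG13640 at least 9.20-fold higher at 100 ng. The highest Tag signal of the 100 ng array itself was larger (3.56), so over that array's own background both rises were smaller.

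Among called genes lower on all 4 Clk arrays than on both controls, the 10 largest falls were those of ec (-4.57, SE 0.16, adjusted p = 1.70e-07), Ctr1A (-3.56), which encodes a copper importer, P5cr (-3.48), an enzyme of proline synthesis, and CG1316 (-3.44). They continued with CG12065 (-3.29), LRR (-3.20), the translation initiation factor subunit eIF3f1 (-3.14), the proteasome subunit Rpn1 (-3.06), CG17078 (-3.01) and the proteasome regulator PI31 (-2.98). At 10 ng these genes differed by between -0.10 (P5cr) and -0.42 (ec), and none passed there. On the 100 ng array ec, Ctr1A, P5cr, CG1316 and CG12065 read between 2.59 (CG1316) and 3.36 (CG12065), under its highest Tag control (3.56), so their fall at that dose and over all doses is a lower bound. With readings under the highest Tag control set to it, the all-dose values were -4.35 for ec, -3.32 for Ctr1A, -3.30 for P5cr, -3.22 for CG12065 and -3.12 for CG1316, which then fell less than LRR and eIF3f1. Without the 100 ng array the 10 falls still passed, at between -1.04 (eIF3f1) and -2.60 (ec). The 5' minus 3' control signal of the 30 and 100 ng arrays was -9.40 and -8.25, against -0.75 in controls.

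Of all 6612 genes, 124 (1.88%) were higher and 506 (7.65%) lower on all 4 Clk arrays than on both controls, where chance gives 6.67% in each direction, and 85 and 424 of them were called. These ranks use the values as deposited, where the median change of all genes at 10 ng was -0.09, against 0.007 after quantile normalization. Counts after scaling are not given here, so the split between higher and lower may follow scaling. The count at all doses rested on the 100 ng array: 397 genes passed without it, 5 without both single-array doses and 2016 without control replicate 1. A fit of 4 Clk arrays against 2 controls that leaves dose in the residual called 0 genes (17 at an unadjusted p under 0.05). The share called higher was 46.1% as deposited, 58.9% after quantile normalization and 59.4% with no filter. It was 10.1% without the 100 ng array (40 higher and 357 lower) and 26.8% without control replicate 1 (540 and 1476).

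Of the core clock list, 4 genes rose over all doses (tim, vri, Clk and Pdp1), cyc fell (-1.11) and 2 did not pass, per (0.35) and cwo (-0.08). The counts were also 4 and 1 when adjusted over the list alone. The calls of Pdp1 (0.20), cyc (-0.55) and slmb (0.19) were lost without the 100 ng array, and those of Pdp1 (0.58) and slmb (0.55) also without control replicate 1, whereas per (0.53) passed without 10 ng replicate 1. Among clock kinases, phosphatases and ubiquitin ligase components, 1 of 8 rose, the F-box gene slmb (0.63, adjusted p = 0.00251), which differed by -0.24 at 10 ng. After quantile normalization or median centring 3 of the 8 passed, slmb, dco and ctrip. The values of the others were 0.34 for dco, 0.25 for ctrip, 0.17 for wdb, 0.10 for Cul3, -0.01 for jet, -0.11 for tws and -0.34 for Usp8, and none passed. The second probe set of wdb read under the highest Tag control on the 100 ng array, so its change is a bound (-3.42 with that reading set to it), and the probe sets of that gene disagreed. sgg, CkIIalpha, CkIIbeta, nmo and mts had no probe set with a single gene symbol here.

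Of 22 gene lists, 19 had at least 3 tested members, and 6 were called over all doses by camera with the preset correlation of 0.01. The core clock (adjusted p = 0.00750), known E-box targets of Clk (adjusted p = 0.00345) and immune response genes (adjusted p = 0.0294) were shifted up. All 5 E-box targets tested are among the 7 core clock genes tested, so these lists are not separate evidence. In both, tim had by far the largest change (6.54), and the core clock list also holds Clk, the transfected gene. Proteasome, ribosomal protein and oxidative phosphorylation genes were shifted down (adjusted p = 3.30e-06, 0.000115 and 4.30e-05). With an estimated correlation all 6 had an adjusted p of 0.833, and fry called 0 lists. With no filter or at face value 3 lists were called, all of them lower, so the calls of the 3 lists shifted up were lost. The 2 clock lists were also lost without 10 ng replicate 2 (adjusted p = 0.172 for the core clock and 0.134 for E-box targets), and the immune list without control replicate 2 (0.102) or the 30 ng array (0.0705). The 3 lists shifted down kept a median below 0 after quantile normalization and median centring, and the 3 shifted up kept one above 0.

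Of 15 immune response genes, 10 rose and 1 fell, among them the antimicrobial peptide genes Mtk (0.67), CecB (0.97) and AttD (0.51) and the NF-kappaB gene Dif (1.02). Without the 100 ng array these 4 calls were lost: Mtk was 0.44 (adjusted p = 0.0509), CecB 0.61 (0.133), AttD 0.36 (0.163) and Dif 0.47 (0.238). AttD (0.46, adjusted p = 0.103) was also lost without control replicate 2. Of 25 proteasome genes, 19 fell and 1 rose, with Rpn7 at -1.71 and Prosalpha6 at -1.27. Of 26 ribosomal protein genes, 15 fell and 0 rose, with RpLP2 at -2.20 and RpS7 at -2.12, although 4 rose after quantile normalization. Of 23 oxidative phosphorylation genes, 17 fell and 0 rose, with the Rieske protein gene RFeSP at -2.97 and SdhB at -1.92, although 5 rose after quantile normalization and 2 after median centring. Adjusted over the list alone, the falls were 20 for the proteasome, 15 for ribosomal proteins and 17 for oxidative phosphorylation, and 10 immune genes rose. Without the 100 ng array these 6 falls still passed but were smaller: Rpn7 -0.66, Prosalpha6 -0.54, RpLP2 -0.63, RpS7 -0.61, RFeSP -1.07 and SdhB -0.87. The calls of Rpn3 (-1.56, or -0.36 without it, adjusted p = 0.115) and RpS18 (-1.68, or -0.27, adjusted p = 0.336) were lost. At 10 ng none of the members of these 4 lists passed, and their medians were 0.01 for immune response, -0.06 for the proteasome, -0.18 for ribosomal proteins and -0.12 for oxidative phosphorylation, where the median of all genes was -0.09. After quantile normalization the 10 ng medians of the proteasome (0.05), ribosomal proteins (0.01) and oxidative phosphorylation (0.04) lay above 0. The 30 and 100 ng arrays, with 5' minus 3' control signals of -9.40 and -8.25, supply the rest of the contrast.

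Other lists were not called over all doses. In the stress lists, 1 heat shock gene rose and 2 fell of 7 (Hsp60A -1.05, Hsp68 -1.05), 1 rose and 4 fell of 10 in the unfolded protein response (Sec61alpha -1.77), and 3 rose and 6 fell of 23 detoxification genes (GstE6 -0.93). In the JNK list, which was called lower without control replicate 1 (adjusted p = 0.0224) or the 100 ng array (0.0143), 3 rose and 4 fell of 9, with the metalloproteinase gene Mmp2 at -3.83 (under the highest Tag control on the 100 ng array, so a bound, -3.65 with that reading set to it) and Jra at -1.84. With an estimated correlation and all 6 arrays the adjusted p of the JNK list was 0.833. Among 11 ecdysone response genes 4 rose and 1 fell (EcR 1.05), and among 10 E(spl) and other bHLH genes 4 rose and 1 fell (Mitf 1.64). Cell cycle genes (2 higher, 4 lower of 19, PCNA -1.12), glycolysis genes (0 higher, 4 lower of 10, Pgk -2.30), lipid metabolism genes (2 higher, 2 lower of 11, SREBP -0.70) and rhythmic output genes (3 higher, 2 lower of 7, Sik3 0.86) made up the rest. The median and the mean differed in sign for rhythmic output (0.33 and -0.05), cell cycle (0.04 and -0.15) and lipid metabolism (0.15 and -0.02). The list median changed sign with scaling for heat shock (-0.07, or 0.06 after quantile normalization), glycolysis (-0.07, or 0.03) and detoxification (-0.03, or 0.06 after median centring). After quantile normalization and after median centring cell cycle genes had 5 higher and 4 lower, and lipid metabolism genes had 5 higher and 2 lower after quantile normalization and 4 and 2 after centring. Adjusted over each list alone the counts were within 1 of these. Of 92 named genes called over all doses, 53 were not called without the 100 ng array. Among them were Hsp60A (-0.26), GstE6 (-0.12), Jra (-0.46), EcR (0.45), Mitf (0.57), PCNA (-0.38), SREBP (-0.28) and Sik3 (0.30). Hsp68 (-0.74), Sec61alpha (-0.66), Mmp2 (-2.53) and Pgk (-0.64) still passed without it. Every one of these lists includes the 2 arrays with the low 5' control signal (-9.40 and -8.25).

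Haemocyte markers were bright in these cells, with Pxn at 14.14 and Col4a1 at 14.56 in controls, and 20 of the 21 on the list were tested. Of these 3 rose and 6 fell over all doses (Pxn -1.54, Hml -0.83), with a list median of -0.22 that became 0.03 after quantile normalization, and the list was not called (adjusted p = 0.430). After quantile normalization or median centring 6 rose and 5 fell, and without the 100 ng array the calls of Pxn (-0.53, adjusted p = 0.0576) and Hml (-0.24, adjusted p = 0.347) were lost. Markers of other cell types were mostly near background: 3 neuron markers, 2 fat body markers, 1 photoreceptor marker and 0 muscle markers were tested, and only the photoreceptor channel gene trpl (-0.65) passed. Its call was lost after quantile normalization (-0.25), where the neuron marker elav passed (0.73), and without control replicate 2 (-0.56), the 30 ng array (-0.44) or the 100 ng array (-0.53). At 10 ng camera also called haemocyte markers (median -0.22), ribosomal proteins (-0.18), heat shock (-0.27) and lipid metabolism genes (-0.18) lower, and immune response genes and E-box targets higher. With an estimated correlation the adjusted p was 0.210 for the E-box targets, 0.708 for ribosomal proteins and 0.683 for the others, and after quantile normalization the medians were 0.01 for ribosomal proteins, -0.08 for haemocyte markers, -0.08 for lipid metabolism and -0.17 for heat shock. No member of these lists other than tim passed at 10 ng over all genes.

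Among the Clk arrays alone, 2149 genes had a positive slope on log10 dose and 1806 a negative one. The 5 steepest rises were in CG16700 (4.35 per 10-fold dose), UGP (4.26), an enzyme gene of UDP-glucose synthesis, tim (3.92), CG43109 (3.85) and vis (3.61). The 5 steepest falls were in ec (-8.16), Mtpbeta (-7.91), a subunit gene of mitochondrial fatty acid oxidation, the splicing factor genes SmD3 (-7.28) and SmB (-7.09), and CG1316 (-6.98). On the 100 ng array ec (2.92) and CG1316 (2.59) read under the highest Tag control (3.56), so their slopes are bounds, -7.57 and -6.08 with those readings set to it. By these bounds Mtpbeta comes before ec, and eIF3f1 (-6.90) takes the place of CG1316. vri (2.82, adjusted p = 0.00124) and CG10514 (2.94, adjusted p = 0.000645) also rose with dose, whereas the slope of Mur2B was -0.50 (adjusted p = 0.400). The 2 probe sets of Timp had opposite slopes, 2.05 and -2.03, both past the threshold. Without the 100 ng array 1563 genes passed, and over all doses the calls of CG16700 (0.69), UGP (0.62), CG43109 (0.05) and vis (0.48) were lost. The 5' control signal (-0.94 at 10 ng, -9.40 at 30 ng and -8.25 at 100 ng) changed along with dose.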

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

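The tests of the rise of tim, Timp, Mur2B and CG10514 and of the spread between the 10 ng arrays were chosen after those results were seen; the 3 tests of the large counts at 30 and 100 ng were written before their results.

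Among control probe sets that no comparison used, AFFX-Dm-M15077-1_at averaged 10.43 over the 4 Clk arrays against 4.05 in controls, and AFFX-Dm-M15077-1_s_at averaged 10.40 against 3.25. Both drew attention because every Clk array lay far above both control arrays. Their signal was 11.22 and 11.42 at 10 ng and 8.58 and 8.26 at 100 ng, so it was lower at the highest dose. That dose is 1 array with a low 5' minus 3' control signal (-8.25), so this is not evidence of a dose effect. The tables used here do not name the transcript they detect, and no biological explanation was tested.

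For the 4647 genes called at 100 ng, a difference in array scaling is argued against, since quantile normalization left 1.08 times as many called. The calls at 30 ng depended on scaling. After quantile normalization their count went from 1097 to 1715 and the share higher from 37.5% to 54.7%. Shortened target RNA predicted that 2 probe sets of a gene would move apart, and their median difference was at least 5.63 times that at 10 ng (12.07 times at 100 ng). Few genes changed at 10 ng, so any large change on a single array could widen this difference. The ratio therefore does not tell shortened RNA from a response to Clk. If a transcript-wide response to Clk were the whole cause, the second probe set of a gene that fell should mostly fall too; the share was 0.495 (47 of 95 genes, 95% exact binomial interval 0.391 to 0.599), under the bound of 0.5 set beforehand, but the interval spans that bound. The requirement that the interval clear the bound was added after the share was seen. By the bound alone this explanation would have been labelled as excluded. However, the first probe set was the brighter and was chosen because it fell, whereas the second may lie too near background to show a fall. The share therefore cannot exclude a transcript-wide response. Dose and 5' signal stay confounded, so a part of these calls may be a response to Clk and a part may be lost 5' signal.

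For the rise of tim, Timp, Mur2B and CG10514 at 10 ng the test of 5' signal loss decides nothing. Their smallest rise was 1.67 against a change of -0.19 in the control signal, but no change under 0.97 could have been called. With the 5' control signal as a covariate the log2 changes were 4.60 for tim (adjusted p = 0.0241), 3.52 for Timp (0.0149), 2.44 for Mur2B (0.0525) and 1.60 for CG10514 (0.242); that covariate varies almost only within the 10 ng pair among the 4 replicated arrays. The calls lost with no filter or at face value go with lower prior degrees of freedom (1.67 and 2.32) and more probe sets tested, and do not weigh against a response to Clk. Such a response is a candidate explanation and remains a hypothesis, found and examined on the same arrays. The AFFX-Dm-M15077-1_at and AFFX-Dm-M15077-1_s_at control probe sets also rose at 10 ng, by 7.17 and 8.17. What they detect is not known here, so a difference between the transfections besides Clk was not excluded.

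The spread between the 10 ng arrays may share an axis with the 30 ng array. The 86 genes at least 1 lower on 10 ng replicate 1 had a median change of -0.68 on the 30 ng array, where the median of all genes was 0.15. There 75 of the 86 were lower, against 2494 of all 6612 genes. Of the 86, 83 were also lower on control replicate 1 than on control replicate 2 (median -0.52, against -0.13 for all genes). Most genes were lower on control replicate 1, 5080 of 6612, so that count is only partly particular to the 86. At 100 ng their median change was -0.15, so the second array with low 5' signal did not show a shift of that size. The 10 ng arrays also differed in the 5' minus 3' control signal (-1.25 and -0.64).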

How the results depend on the processing

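The face-value scale, leaving out both single-array doses, the 5' covariate and the list tests at 10 ng and at face value were chosen after seeing the data. Signal over background limits the dim genes, and the cause of the changes given here was not tested unless stated.

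At 10 ng (4 genes), 0 passed with no filter, 0 at face value, 0 at face value with robust moderation, 2 with the 5' control signal as a covariate, 10 with robust moderation and 13 with the replicate block. Leaving out 1 array gave 1 to 12. Only 2 pairs share a number and their deviations correlated at r = 0.33 across probe sets (rho = 0.17), which does not establish that the arrays were paired. With the replicate block 3185 genes passed over all doses, 1148 at 30 ng, 4573 at 100 ng and 3485 for the slope.

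At 30 ng (1097 genes), 450 passed with no filter, 1715 after quantile normalization, 1757 after median centring, 1814 with robust moderation, 456 at face value and 434 at face value with robust moderation, and 1777 at an adjusted p under 0.10, by construction more. Leaving out 1 array gave 753 to 1119 at 30 ng and 4156 to 4767 at 100 ng, where every setting run stayed within 1.5 times the count. The slope gave 1563 to 4737. Leaving out the 30 ng array at 30 ng, or the 100 ng array at 100 ng, can give no value.

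Over all doses (3295 genes), limma called 0 in the 2-group fit (17 unadjusted), 5 without the 30 and 100 ng arrays, and 397 to 3507 when 1 array was left out. The median of all genes was 0.04, and 0.14 after quantile normalization; at 100 ng it was 0.05 and 0.25.

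Without the 30 and 100 ng arrays, which leaves the 10 ng change by construction, the sign of a called gene turned for slmb (-0.24), CG16700 (-0.13), CG43109 (-0.15), vis (-0.31), SmD3 (0.049), Sik3 (-0.15), kay (-0.28), stv (-0.28), Herp (-0.11), GstS1 (-0.024), tgo (-0.11), Max (-0.16), Gadd45 (0.040), puc (-0.32), Eip93F (-0.13), Hr39 (-0.28), Hr96 (-0.040), Pgk (0.039) and Acsl (-0.37). The sign also turned with the mean of probe sets for wdb (-1.65) and kay (-0.22). Eip93F was -0.039 without the 100 ng array and 1.54 without the 30 ng array.

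Of gene lists (6 called), 0 were called with an estimated correlation, 0 by fry, 0 at 10 ng with an estimated correlation, 3 with no filter, 3 at face value, 7 with the replicate block and 4 to 7 when 1 array was left out. At 10 ng the test turned direction for lipid metabolism (adjusted p = 0.0257) and the proteasome (0.967, or 0.990 with an estimated correlation), and, with no call at either, for clock kinases, rhythmic output and bHLH genes. Over 107 named results at all doses, 1919 alternative values kept their direction and side of the threshold, 253 no longer passed, 15 newly passed, and 40 changed sign, 22 of them with a call before or after.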

Other observations

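These values were chosen after the data were seen. Of the 6612 genes, 76 were higher at each step of dose with all 4 Clk arrays above both controls, and 68 of these were called over all doses. Irrespective of order, 1.88% of genes had all 4 Clk arrays above both controls, where chance gives 6.67%. The number expected by chance in this order was not computed, and the calls come from the same arrays. The count is therefore no evidence of a dose-ordered response. tim (3.65, 8.37, 9.85 and 12.35), vri (7.02, 8.31, 9.57 and 11.15) and CG10514 (3.22, 4.89, 6.22 and 7.84) had this order in controls, 10, 30 and 100 ng.

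Between the 2 10 ng arrays 88 genes were at least 2-fold apart, against 20 between the controls. The widest were the RNA export factor gene Nxf3 (9.18-fold), fend (5.64-fold) and hpRNA:CR33940 (4.47-fold), and cwo (3.86-fold), tara, dnc and bun were among the 20 widest. The control probe set AFFX-Dm-U43284-1_s_at read 14.80 in controls, 12.19 at 30 ng and 10.30 at 100 ng.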
